A study of Homo sapiens with 6 samples.

How the data were processed

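RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer cell line, in 3 groups of 2 libraries. The control cells carried a non-targeting short hairpin RNA (shRNA). The other groups lacked PARP1 through knockout (KO) and carried an shRNA against EZH2 or against SUZ12. EZH2 and SUZ12 are subunits of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. Per the labels' protocols, total RNA was column-purified after 2 days of culture and libraries were made with a stranded poly(A) kit. Groups were taken from the sample titles, and columns were matched to samples by their names, which spell the knockout "PAPR1".

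The authors deposited raw read counts per gene symbol, 1 column per library, with replicates not pooled. The submitters' processing notes name STAR, R 3.2.5, GenomeStudio 2010.1 and the GRCh38 build, without saying which step each served. The gene annotation, the STAR version and the strand setting of the counting are not given in the sources used here, so reads of a gene and of its antisense partner may not have been told apart. Of 29748 entries in the deposited counts, 4 name no gene (unmapped, multimapping, no feature and ambiguous reads). They held 16.5 to 21.0% of all counts per library and were left out of library sizes and tests. Multimapping reads made up 7.21 to 10.4%, so genes with near-identical copies, such as MAGEA3, ALPP and the ribosomal protein genes with their pseudogenes, are counted with less certainty. Of the 29744 genes, 8814 had no count in any library, and 14192 passed edgeR's filterByExpr by group and were tested.

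Gene counts per library ranged from 20135270 to 22782742. A floor of 3 counts corresponded to 0.134 to 0.153 CPM, which are counts scaled to the effective library size by the trimmed mean of M values (TMM) and computed here from the deposited counts. Floors and counting intervals (95%) cover counting error only. Where every library of a group was at 0, the fold is a lower bound against 3 counts over the group.

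Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. A single edgeR quasi-likelihood fit (robust) held all 3 groups, which share 1 estimate of the spread with 3 residual degrees of freedom. The 3 contrasts were each depleted line against control and the depleted lines against each other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors (SE) were derived from the log2 fold change and its F statistic. No group lacked PARP1 alone, EZH2 alone or SUZ12 alone, so no contrast isolates 1 of these genes. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 2 libraries per group an exact permutation test of a single gene cannot go below p = 0.333.

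Gene groups were tested by limma's camera on voom-transformed counts with an inter-gene correlation preset at 0.01, two-sided, and with Benjamini-Hochberg adjustment over the lists within each contrast. The 27 lists, the tests and the alternatives were fixed before the data were examined, except where stated. Lists of fewer than 5 tested members were not tested. The list of mitochondrially encoded genes had 0 members among the symbols in the deposited counts, which left 26 lists. Beside each call of the main fit, the adjusted p with an inter-gene correlation estimated from the data is given. Where that estimate is far above the preset, the preset p treats members that vary together as nearly independent.

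Named genes followed a rule fixed beforehand. PARP1, EZH2 and SUZ12 are always named. For each contrast the 10 largest rises and 10 largest falls in log2 fold change were taken among called genes with a mean of at least 5 CPM in the higher group and libraries that do not overlap between groups. Symbols of uncharacterised loci, small RNAs, antisense transcripts and pseudogenes were excluded. The 6 genes that rose and the 6 that fell most in both lines, at most 2 rises and 2 falls per list and contrast with control, and at most 6 genes called in opposite directions were added. A list with no called member gives its 2 most abundant members. The rule named 117 genes, some of which are summarised only by counts.

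Positions of genes are those of GENCODE version 29 on GRCh38. Of the symbols in the deposited counts, 23643 matched a gene there, directly or through a unique synonym. Transcript lengths came from the same release and covered 94.5% of tested genes. They are those of the longest annotated transcript of a gene, protein-coding where there was one.

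Comparisons with the same 2 controls share their chance values. Unchanged groups were therefore simulated against those controls in 100 draws. The edgeR procedure was tested on simulated data with 200 genes changed. In the shEZH2 contrast it recovered 31% of 2-fold and 99% of 4-fold changes (13731 genes in the fit), and 8.45% of its calls were unchanged genes. In the shSUZ12 contrast it recovered 33% and 99% (13728 genes), with 5.71% of calls unchanged. Between the depleted lines it recovered 32% and 94% (13718 genes), with 8.70% of calls unchanged. Both simulations gave each gene the same spread in every library, whereas the real shEZH2 replicates differed more than the other pairs. Changed genes were drawn only from those above a minimum count. These rates may therefore not hold for the real contrasts.

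Alternatives were median-of-ratios and upper-quartile scaling, no filter or a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit on the 2 compared groups, a test against a 1.5-fold change, adjusted p under 0.01, and leaving out each library in turn. For lists they were an estimated correlation and limma's fry. After seeing the data, limma-voom with sample weights and removal of each library's trend with transcript length were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.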

Results

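The series profiled messenger RNA of MDA-MB-231 breast cancer cells in 6 libraries. There were 2 libraries each of cells with a non-targeting shRNA (control), of PARP1 knockout cells with an shRNA against EZH2 (the shEZH2 line) and of PARP1 knockout cells with an shRNA against SUZ12 (the shSUZ12 line). PARP1 is the main enzyme of poly(ADP-ribose) synthesis at DNA breaks. The comparisons ask what changes when PARP1 is knocked out and a PRC2 subunit is targeted by an shRNA. Gene counts were 22782742 and 20843336 in control replicates 1 and 2, 20956245 and 20568174 in the shEZH2 line, and 21657404 and 20135270 in the shSUZ12 line. The shEZH2 replicates stood apart from each other: 15.3% of tested genes differed over 2-fold between them, against 3.24% in control and 1.61% in the shSUZ12 line. Of 150 calls of named genes over the 3 contrasts, 14 held without control replicate 1 or without control replicate 2, 54 and 55 without shSUZ12 replicate 1 or 2, and 147 without shEZH2 replicate 1 or 2, and none changed direction.

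The targeted genes were examined for each library. PARP1 (chromosome 1, 226360691 to 226408079, minus strand, GRCh38) stood at 425 and 361 CPM in control, 33.6 and 28.6 CPM in the shEZH2 line and 28.7 and 26.6 CPM in the shSUZ12 line. It fell by 3.66 ± 0.20 (SE) on the log2 scale in the shEZH2 line and fell by 3.83 ± 0.20 in the shSUZ12 line (n = 2 per group; adjusted p = 0.000599 and 0.000842, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). EZH2, the methyltransferase subunit of PRC2 (chromosome 7, 148807383 to 148884321, minus strand), stood at 199 and 188 CPM in control and 53.1 and 63.5 CPM in the shEZH2 line. It fell by 1.73 ± 0.18 there (adjusted p = 0.00539 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without control replicate 1 or 2 that edgeR adjusted p was 0.115 or 0.0840. In the shSUZ12 line EZH2 was at 201 and 221 CPM, with a log2 fold change of 0.13 ± 0.17. SUZ12 (chromosome 17, 31937018 to 32001045, plus strand) stood at 134 and 133 CPM in control and 76.1 and 70.3 CPM in the shSUZ12 line. Its log2 fold change there was -0.87 ± 0.37 and did not pass the test (edgeR adjusted p = 0.377). It passed without shEZH2 replicate 1 or 2 (edgeR adjusted p = 2.43e-06 and 2.31e-06). SUZ12 differed between the shEZH2 replicates, at 130 and 53.1 CPM. The log2 fold change of SUZ12 in the shEZH2 line was -0.54 ± 0.37. It was -1.33 without replicate 1, where the shEZH2 line rested on 1 library.

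**Figure D1:**
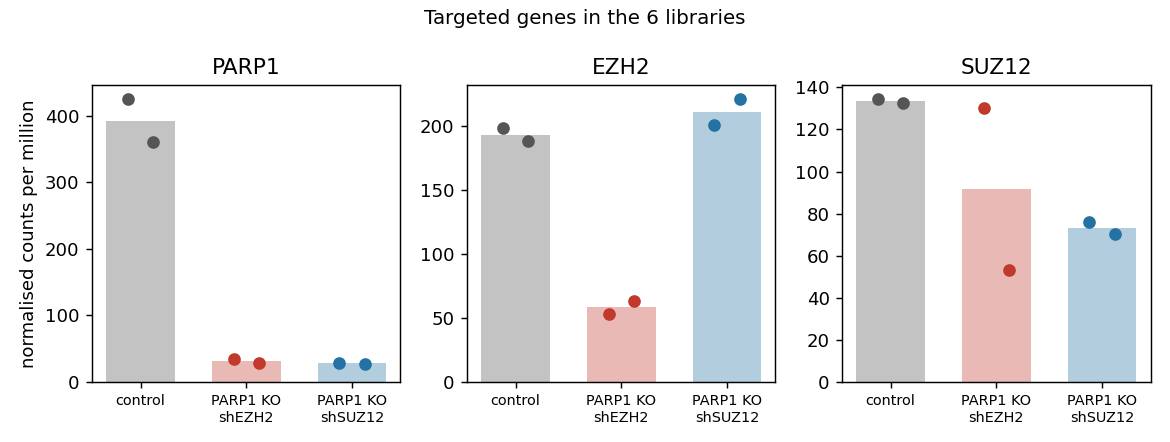
CPM (vertical axis) of PARP1, EZH2 and SUZ12 in the 3 groups (horizontal axis); points are single libraries and bars the mean of 2. PARP1 was at 33.6 CPM or below in all 4 depleted libraries, and SUZ12 was at 130 and 53.1 CPM in the 2 shEZH2 libraries.

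The shEZH2 line was compared with control to find the genes that change when PARP1 and EZH2 are both depleted. AMPH, which encodes the endocytic protein amphiphysin, had 0 counts in control and 9.84 and 9.81 CPM in the shEZH2 line, at least 142-fold higher. FOXR2, a forkhead factor, and LDB2, a LIM-domain binding protein, also had 0 counts in control and were at least 203-fold and 113-fold higher. CXCR4, the chemokine receptor for CXCL12, rose by 5.08 ± 0.41 on the log2 scale, and HCLS1, a signalling adaptor of blood cells, rose by 4.24 ± 0.22. Among the falls, LSR, a receptor found at tricellular junctions, went from 26.5 and 28.9 CPM to 0.241 and 0.409 CPM and fell by 6.40 ± 0.34. CDH11, a mesenchymal cadherin, fell by 5.37 ± 0.33, and L1CAM, a neural adhesion molecule, fell by 3.83 ± 0.37. Among these 8 genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p from 0.000599 to 0.00496 (n = 2 per group).

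Further rises in the shEZH2 line included SERPINB2, an inhibitor of plasminogen activators (42.0-fold), KLHL13 (44.3-fold), GMFG (31.7-fold), the lymphoid factor IKZF3 (24.5-fold) and the phospholipase gene PLCH2 (23.1-fold). SLC9A2, a sodium-proton exchanger, had so few control counts that its ratio of 111 carries a counting interval of 30.4 to 923. Further falls were LHFPL4 (64.8-fold), AGMAT (27.6-fold), CYP24A1, whose enzyme inactivates vitamin D (25.3-fold), the receptor GPR110 (22.9-fold), the muscle kinase MUSK (19.2-fold), TENM1 (13.6-fold) and INHBB, an activin subunit (12.7-fold). In all, 957 of 14192 genes were called, 503 higher and 454 lower, and 3799 had an unadjusted p under 0.05. The count rested on single libraries: it was 7 without control replicate 1, 5 without control replicate 2, 198 and 196 without shSUZ12 replicate 1 or 2, and 7775 and 4021 without shEZH2 replicate 1 or 2. Here and in the other contrasts, a group left with 1 library was assumed to vary like the others.

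Genes of the translation and respiration machinery were higher in the shEZH2 line. Of 74 cytosolic ribosomal protein genes, 6 rose and 68 did not pass the test, and adjusted over the list alone 50 rose. RPLP1 rose by 1.57 ± 0.29 and RPL4 by 1.02 ± 0.21. The list as a whole was higher (median log2 fold change 0.76; adjusted p = 3.87e-17, limma's camera with Benjamini-Hochberg adjustment). With an estimated correlation this was adjusted p = 0.863. Of 49 nuclear-encoded oxidative phosphorylation genes, 3 rose (adjusted over the list alone, 7), among them UQCRH with 117 and 111 CPM in control against 284 and 422 CPM. This list was also higher (median 0.54, camera adjusted p = 1.31e-06 with Benjamini-Hochberg adjustment). Its estimated correlation was 0.734, with which camera gave adjusted p = 0.863, and fry gave adjusted p = 0.416. Both lists differed between the shEZH2 replicates: their medians were 0.35 and 0.10 above control in shEZH2 replicate 1 and 1.13 and 0.88 above it in replicate 2. Without replicate 2 the medians over the group were 0.38 and 0.13. With each library's trend with transcript length removed they were 0.41 and 0.27, with 27 ribosomal and 12 oxidative phosphorylation genes called higher over all genes.

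The epithelial, interferon-stimulated and cholesterol lists had medians below control in the shEZH2 line. Above control were 9 of 33, 20 of 43 and 5 of 25 members in turn. Of 33 epithelial adhesion and keratin genes, 5 fell and 0 rose (adjusted over the list alone, 7 fell and 1 rose). ESRP2, a splicing factor of epithelial cells, fell by 3.12 ± 0.42 and the tight junction gene CLDN1 fell by 2.50 ± 0.40 (list median -0.44; camera adjusted p = 0.0106 with Benjamini-Hochberg adjustment). Of 43 interferon-stimulated genes, 8 fell and 0 rose (adjusted over the list alone, 13 fell and 2 rose). SAMD9L fell by 2.13 ± 0.23, and DDX58, the cytosolic RNA sensor RIG-I, fell by 1.31 ± 0.20 (list median -0.27; camera adjusted p = 0.0489 with Benjamini-Hochberg adjustment). Of 25 cholesterol synthesis genes, 1 fell, SREBF2, the transcription factor that drives them, by 0.92 ± 0.21 (adjusted over the list alone, 0; list median -0.67; camera adjusted p = 0.0106 with Benjamini-Hochberg adjustment). For each of these 3 lists the camera value was adjusted p = 0.863 with an estimated correlation. The estimates for the epithelial, interferon-stimulated and cholesterol lists were -0.0113, 0.220 and 0.721 in turn. Interferon-stimulated genes had a median of -0.57 against control in shEZH2 replicate 1 and -0.02 in replicate 2. Without replicate 1 the medians of the epithelial, interferon-stimulated and cholesterol lists were -0.36, -0.03 and -0.60 and the camera adjusted p was 0.177, 0.776 and 0.634 in turn, and without control replicate 2 it was 0.0790 for interferon-stimulated and 0.341 for cholesterol genes. For interferon-stimulated genes it was also 0.0547 and 0.0544 without shSUZ12 replicate 1 or 2.

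Single members of other groups moved in both directions in the shEZH2 line. Among secreted factors that act on myeloid cells, 3 of 25 rose and 3 fell (adjusted over the list alone, 4 and 5). VEGFA, the main angiogenic growth factor, was at 205 and 211 CPM in control and fell by 1.70 ± 0.16 to 62.9 and 64.8 CPM. TGFB2 fell by 1.74 ± 0.24, and PGF, a relative of VEGFA, rose by 1.78 ± 0.22. SPP1, which encodes osteopontin, had 2 control counts and a ratio of 102 (counting interval 28.0 to 852). Among mesenchymal genes 6 of 33 rose and 4 fell (adjusted over the list alone, 7 and 9). SNAI1, a repressor of epithelial genes, rose by 2.47 ± 0.32 and the collagen gene COL6A2 by 1.58 ± 0.18, while the receptor kinase AXL fell by 1.10 ± 0.21. Among NF-kB target genes 4 of 37 rose and 3 fell (adjusted over the list alone, 8 and 5). ICAM1, a leukocyte adhesion molecule, rose by 1.86 ± 0.22, TRAF1 rose by 1.13 ± 0.22, BIRC2 fell by 1.29 ± 0.18 and TNFSF10, the death ligand TRAIL, fell by 2.17 ± 0.38. MYC fell by 1.11 ± 0.22, and PHGDH, which opens serine synthesis, rose by 1.92 ± 0.22.

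The shSUZ12 line was compared with control in the same way. SERPINB2 was at 0.135 and 0.0950 CPM in control and 8.23 and 9.63 CPM in the shSUZ12 line, and rose by 6.20 ± 0.39 on the log2 scale. AMPH was at 7.02 and 7.34 CPM, at least 103-fold above its 0 control counts. CXCR4 rose by 5.12 ± 0.41, HCLS1 by 3.49 ± 0.21 and PIK3CG, the catalytic subunit of PI3-kinase gamma, by 4.14 ± 0.57. AGMAT fell by 6.15 ± 0.61, INHBB fell by 5.69 ± 0.34, and LSR fell by 5.13 ± 0.31. ITGB2, the leukocyte integrin beta chain, fell by 4.25 ± 0.31 and the adhesion molecule MCAM fell by 3.50 ± 0.32. Over these 10 genes the adjusted p ran from 0.000842 to 0.0179 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 per group).

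Other rises in the shSUZ12 line were RASEF (15.3-fold), the proteoglycan gene SPOCK1 (12.7-fold), FRMPD3 (10.9-fold), the netrin receptor NEO1 (7.95-fold) and NRK (7.76-fold). Other falls were CDH11 (28.8-fold), LHFPL4 (24.1-fold), CYP24A1 (19.5-fold), TNS4 (15.6-fold) and ALPP, placental alkaline phosphatase (9.33-fold). The contrast called 228 of 14192 genes, 102 higher and 126 lower, and 1857 had an unadjusted p under 0.05. The spread between the shEZH2 replicates entered this count: without shEZH2 replicate 1 or 2 it was 2917 or 2929, and a fit on the 2 compared groups called 2876. It was 9 without either control library and 14 and 16 without shSUZ12 replicate 1 or 2.

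Inflammatory NF-kB target genes were higher in the shSUZ12 line: 3 of 37 rose and 1 fell (adjusted over the list alone, 14 and 1). IL8, the neutrophil chemokine, rose by 2.73 ± 0.38 and ICAM1 by 1.59 ± 0.22, while BIRC2 fell by 1.08 ± 0.18 (list median 0.46; camera adjusted p = 1.34e-05 with Benjamini-Hochberg adjustment; adjusted p = 0.311 with an estimated correlation). In the shEZH2 line 25 of the 37 NF-kB target genes were above control (median 0.31, camera adjusted p = 0.0809 with Benjamini-Hochberg adjustment). Between the lines 0 of 37 were called, with 7 higher and 1 lower in the shSUZ12 line adjusted over the list alone. The median there was 0.17 (camera adjusted p = 0.176 with Benjamini-Hochberg adjustment). Of 33 epithelial genes 5 fell and 0 rose in the shSUZ12 line (adjusted over the list alone, 6 and 1). CLDN1 fell by 3.10 ± 0.42 and ESRP2 fell by 3.12 ± 0.42 (list median -0.38; camera adjusted p = 1.34e-05 with Benjamini-Hochberg adjustment; adjusted p = 0.272 with an estimated correlation).

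Cholesterol synthesis genes stood higher in the shSUZ12 line as a list, with 22 of 25 members above control and 0 called over all genes or adjusted over the list alone (median 0.48; camera adjusted p = 0.000826 with Benjamini-Hochberg adjustment; adjusted p = 0.834 with an estimated correlation). Hypoxia and glycolysis genes were also higher as a list, with 0 of 41 called and 2 higher adjusted over the list alone (median 0.18; camera adjusted p = 0.00783 with Benjamini-Hochberg adjustment; adjusted p = 0.691 with an estimated correlation). Cell cycle genes were lower as a list, with 50 of 57 members below control and 0 called by either adjustment (median -0.14; camera adjusted p = 0.0107 with Benjamini-Hochberg adjustment; adjusted p = 0.691 with an estimated correlation). Their most abundant members, TOP2A and MKI67, had log2 fold changes of -0.13 ± 0.31 and -0.26 ± 0.35. Without control replicate 1 the camera adjusted p was 0.562 for cholesterol and 0.265 for cell cycle genes. Without shSUZ12 replicate 1 it was 0.236 for cholesterol, 0.140 for cell cycle and 0.204 for hypoxia genes.

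**Figure D2:**
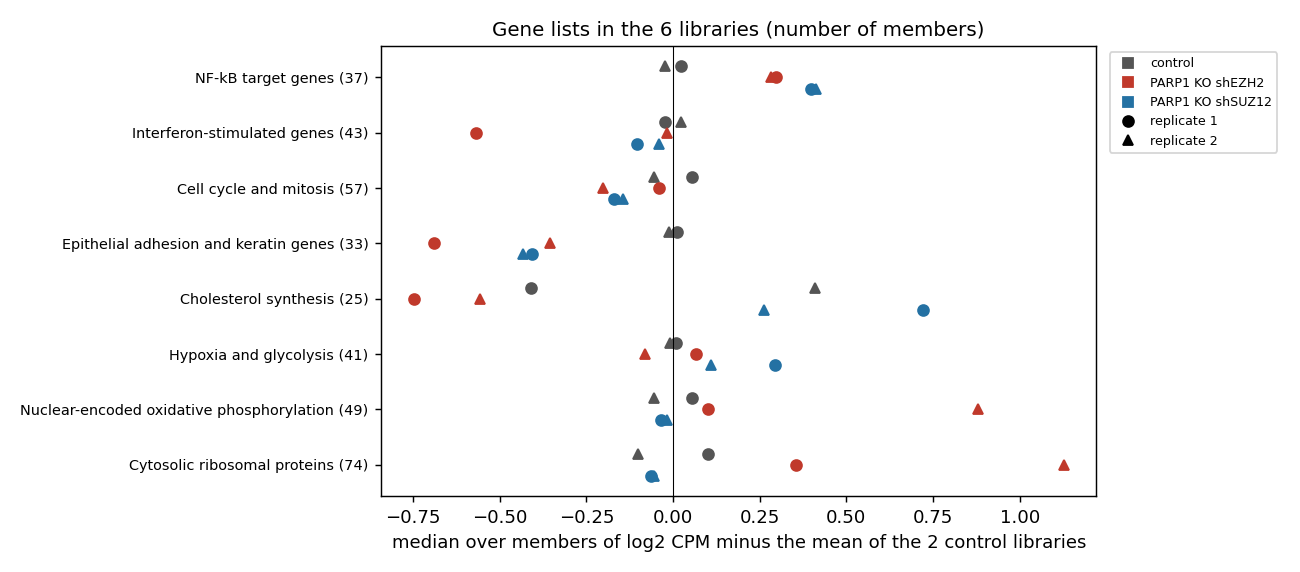
Median over the members of each gene list of log2 CPM minus the mean of the 2 control libraries (horizontal axis), for the lists called in any contrast (vertical axis, members in brackets); circles are replicate 1 and triangles replicate 2. Ribosomal protein genes were at 0.35 and 1.13 in the 2 shEZH2 libraries, and cholesterol synthesis genes at -0.41 and 0.41 in the 2 control libraries.

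The depleted lines were compared directly to find genes that differ between them. CEBPA, a myeloid and adipose transcription factor, was at 9.60 and 12.8 CPM in the shEZH2 line and 0.179 and 0.0954 CPM in the shSUZ12 line, a log2 difference of -6.28 ± 0.42 (shSUZ12 minus shEZH2). The mucin genes MUC5AC and MUC5B were likewise lower in the shSUZ12 line, with log2 differences of -5.32 ± 0.38 and -5.06 ± 0.54, as was ID3, an inhibitor of differentiation factors, at -3.20 ± 0.35. VEGFA was higher in the shSUZ12 line, at 295 and 288 CPM against 62.9 and 64.8 CPM. ITGB8, an integrin that activates TGF-beta, was higher by 4.92 ± 0.62, ADAMTS6, a matrix protease, by 4.07 ± 0.39 and L1CAM by 3.31 ± 0.37. EZH2 itself was higher by 1.86 ± 0.18 (edgeR adjusted p = 0.00917 with Benjamini-Hochberg adjustment). Without control replicate 1 or 2 that edgeR adjusted p was 0.0822 or 0.0791, and without shSUZ12 replicate 1 or 2 it was 0.132 or 0.130. SUZ12 had a log2 difference of -0.32 ± 0.37 (edgeR adjusted p = 0.607), which was 0.46 without shEZH2 replicate 1 and -0.86 without replicate 2. For CEBPA, MUC5AC, MUC5B, ID3, ITGB8, ADAMTS6 and L1CAM edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p from 0.00460 to 0.0216 (n = 2 per group).

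The direct contrast called 216 of 14192 genes, 103 higher and 113 lower in the shSUZ12 line, and 3387 had an unadjusted p under 0.05. Others higher were SLCO4C1 (11.1-fold), CCDC120 (7.73-fold), BMF, a pro-apoptotic BH3 protein (7.10-fold), PAPPA2 (6.11-fold) and FILIP1L (5.60-fold). Others lower were MAGEC2 (31.8-fold), MEGF6 (28.9-fold), SUSD3 (17.7-fold), GMFG (15.4-fold), CREB3L3 (12.1-fold) and ELF3 (9.40-fold). The count was 1 without control replicate 1 or 2 and 0 without shSUZ12 replicate 1 or 2 by edgeR, and 7537 and 3419 without shEZH2 replicate 1 or 2. DESeq2 called 1304.

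Cholesterol synthesis genes were higher in the shSUZ12 than in the shEZH2 line, in 24 of 25 members. SREBF2 alone was called, and 14 were higher adjusted over the list alone (median 0.98; camera adjusted p = 2.01e-07 with Benjamini-Hochberg adjustment; adjusted p = 0.766 with an estimated correlation). Ribosomal protein genes were lower in all 74 members, with 0 called and 66 lower adjusted over the list alone (median -0.82; camera adjusted p = 5.84e-22 with Benjamini-Hochberg adjustment). Oxidative phosphorylation genes were lower in 47 of 49 members, with 0 called by either adjustment (median -0.60; camera adjusted p = 3.70e-09 with Benjamini-Hochberg adjustment). Both also had a camera adjusted p = 0.766 with an estimated correlation, which was 0.917 and 0.734 in turn. Without shEZH2 replicate 2, the library with the highest ribosomal protein counts, their medians were -0.40 and -0.21. With the length trend removed they were -0.42 and -0.25, with 16 and 3 genes called lower over all genes.

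The calls of both comparisons with control overlapped. In both lines 65 genes rose, led by AMPH, SERPINB2, CXCR4, PIK3CG, RASEF and HCLS1, and 69 fell, led by LSR, CDH11, AGMAT, LHFPL4, CYP24A1 and INHBB. Independent lists of these sizes would share 3.62 rising and 4.03 falling genes, and simulated unchanged groups against the same controls shared 0.04 and 0. Unchanged groups are expected to have almost no calls to share, so these simulated values are not a reference for lists of these sizes. The correlation of the fold changes across 14192 genes, which are not independent replicates, was 0.620 against a simulated 0.499. Their covariance was 0.374 against 0.0615, a difference of 0.313. The sign of the fold change was the same in 62.3% of genes, against 66.7% in the simulated groups (SD 0.481). The simulation gave each gene the same spread in every library. The real replicates were unequal: the SD of their log2 difference was 0.719 in shEZH2, 0.375 in control and 0.303 in shSUZ12 libraries. The simulated correlation and share of equal signs are therefore not matched references, and no conclusion is drawn from them. The 2 controls cannot be divided, so part of the shared change may come from these shared libraries. Both lines are also knockout cells that lack PARP1, whereas the control is labelled wild-type. A common effect of reducing a PRC2 subunit therefore cannot be told apart from loss of PARP1 or from selection or passage of the knockout cells. The shared total of 134 was 6 and 4 without control replicate 1 or 2, 14 and 15 without shSUZ12 replicate 1 or 2, and 1523 and 1415 without shEZH2 replicate 1 or 2. In opposite directions 4 genes were called, against 7.73 for independent lists. The simulated groups had 0, which is no reference either, since almost no calls are expected in them. CEBPA rose by 3.63 ± 0.33 in the shEZH2 line and fell by 2.65 ± 0.49 in the shSUZ12 line. That fall passed narrowly (edgeR adjusted p = 0.0477 with Benjamini-Hochberg adjustment). Both shSUZ12 libraries were near the floor of 3 counts for this gene (0.134 and 0.143 CPM). MUC5AC rose by 2.43 ± 0.32 and fell by 2.89 ± 0.35. LRP1, an endocytic receptor, fell by 0.87 ± 0.18 and rose by 1.46 ± 0.18, and ADAMTS6 fell by 1.94 ± 0.40 and rose by 2.13 ± 0.33.

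**Figure D3:**
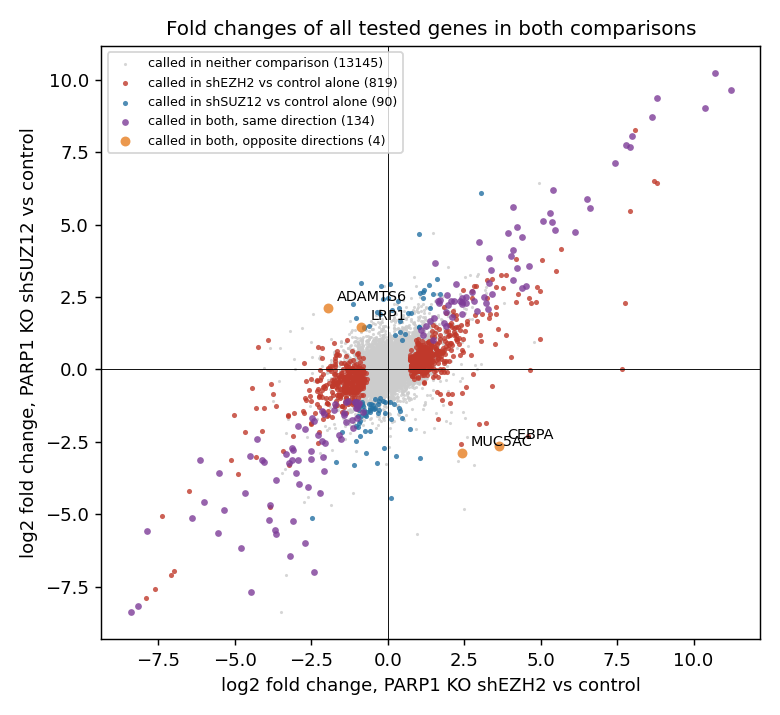
Log2 fold change of each of the 14192 tested genes in the shEZH2 line against control (horizontal axis) and in the shSUZ12 line against control (vertical axis), coloured by the contrasts in which the gene was called. The 134 genes called in both in 1 direction lie in the lower left and upper right, and the 4 named genes lie in the other quadrants.

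The remaining lists were not called in any contrast by camera as fixed beforehand. With the length trend removed, secreted factors and antigen presentation genes were called between the lines (camera adjusted p = 0.0148 and 0.0256 with Benjamini-Hochberg adjustment). With the trend kept and an estimated correlation, camera gave adjusted p = 0.766 for both. In the main fit no PRC2 or PRC1 subunit other than those targeted was called among 28 (0 adjusted over the list alone). With the length trend removed, 3 of them rose and 2 fell in the shEZH2 line, and 0 rose and 1 fell in the shSUZ12 line. PHC2 had log2 fold changes of 0.48 ± 0.19 and 0.41 ± 0.19 in the shEZH2 and shSUZ12 lines and PHF19 of 0.08 ± 0.18 and -0.21 ± 0.18. Of 22 other PARP family and ADP-ribose genes, TIPARP fell by 1.03 ± 0.22 in the shEZH2 line (adjusted over the list alone, 1 rose and 1 fell) and 0 were called in the shSUZ12 line. Of 47 homologous recombination and fork genes, 2 rose in the shEZH2 line, CHEK2 by 1.08 ± 0.22 and RPA2 by 0.82 ± 0.18, and MRE11A fell by 0.99 ± 0.23 (adjusted over the list alone, 2 rose and 0 fell), with 0 called in the shSUZ12 line. Of 25 base excision genes, SMUG1 and ALKBH2 rose in the shEZH2 line by 1.19 ± 0.19 and 1.18 ± 0.25 (adjusted over the list alone, 2 rose and 1 fell), and 0 were called in the shSUZ12 line. With the length trend removed, 2 recombination genes rose and 1 fell in the shSUZ12 line. The spread between the shEZH2 replicates entered these counts and those of the lists that follow. A count of 0 in the shSUZ12 line therefore does not show that the genes were unchanged.

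Of 47 HOX and other developmental factors, 3 rose and 4 fell in the shEZH2 line (adjusted over the list alone, 5 and 5) and 1 rose and 1 fell in the shSUZ12 line (1 and 2). POU3F2 rose by 2.43 ± 0.37 and 2.26 ± 0.37, and IRX2 had 0 counts in both lines, at least 23.0-fold and 24.7-fold lower. Of 29 p53 targets, TP53INP1 fell by 1.67 ± 0.30 in the shEZH2 line and CDKN1A, the cell cycle inhibitor p21, rose by 1.24 ± 0.22 in the shSUZ12 line (adjusted over the list alone, 1 rose and 2 fell, and 1 and 1). Of 16 senescence genes, IGFBP3 fell by 1.74 ± 0.21 and 1.42 ± 0.21 in the lines, GDF15 rose by 1.71 ± 0.27 in the shEZH2 line and CDKN1A rose in the shSUZ12 line (adjusted over the list alone, 1 and 1, and 1 and 2). Of 33 matrix proteases and regulators, 1 rose and 4 fell in the shEZH2 line, PLAT by 1.67 ± 0.29 among the falls, and 2 rose in the shSUZ12 line (adjusted over the list alone, 4 and 7, and 3 and 0). Of 26 immediate early genes, 3 rose and 1 fell and then 1 rose, with EGR1 up by 1.72 ± 0.31 and 2.39 ± 0.32 (adjusted over the list alone, 4 and 3, and 7 and 1). Of 34 unfolded protein and amino acid response genes, PHGDH rose in both lines and PSAT1 fell by 0.98 ± 0.21 in the shEZH2 line (adjusted over the list alone, 1 and 2, and 1 and 0). Of 26 antigen presentation genes, CIITA and CTSS fell by 1.75 ± 0.29 and 1.51 ± 0.28 in the shEZH2 line (adjusted over the list alone, 0 and 2), and 0 were called in the shSUZ12 line (1 and 0). The median of this list in the shEZH2 line was 0.36 without shEZH2 replicate 1 and -0.24 without replicate 2, where camera gave adjusted p = 0.354 and 0.00189 with Benjamini-Hochberg adjustment. Between the lines those camera values were 0.527 and 0.000160.

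In the shSUZ12 line the secreted factors SPP1, IL8 and CXCL1 rose among 25 (adjusted over the list alone, 8 rose and 3 fell), TNC rose by 2.06 ± 0.27 and CDH11 fell among 33 mesenchymal genes (2 and 3), and IFI44L and TRIM22 rose by 1.94 ± 0.29 and 1.99 ± 0.30 among 43 interferon-stimulated genes (2 and 5). Of 8 tested cancer-testis genes, MAGEC2 rose by 2.41 ± 0.53 in the shEZH2 line and MAGEA3 and MAGEC1 fell by 4.44 ± 0.69 and 2.05 ± 0.36 in the shSUZ12 line (adjusted over the list alone, 1 and 0, and 0 and 3). Between the lines MAGEC1, MAGEC2 and MAGEA3 were lower in the shSUZ12 line (adjusted over the list alone, 4; list median -1.84; camera adjusted p = 0.0863 with Benjamini-Hochberg adjustment; adjusted p = 0.766 with an estimated correlation and 0.0145 by fry). Without control replicate 1 or 2 that camera value was 0.0438 or 0.0391, without shSUZ12 replicate 1 or 2 it was 0.0166 or 0.0317, without shEZH2 replicate 1 or 2 it was 0.210 or 0.136, and with the length trend removed it was 0.111. Of 16 neuronal genes, SCN2A and GABRE rose by 3.07 ± 0.48 and 2.23 ± 0.51 and L1CAM fell in the shEZH2 line (adjusted over the list alone, 3 and 4), with 0 called in the shSUZ12 line. Of 16 luminal line markers, 3 rose in the shEZH2 line, CA12 by 1.22 ± 0.23 among them (adjusted over the list alone, 4 and 0), and 0 in the shSUZ12 line (1 and 0). Of 10 tested fibroblast and endothelial markers, 4 rose and 2 fell in the shEZH2 line (adjusted over the list alone, 4 and 3) and KDR fell by 2.53 ± 0.46 in the shSUZ12 line (1 and 3). Of 8 tested leukocyte markers, LAPTM5 rose by 1.48 ± 0.17 and 1.03 ± 0.17 in the lines and CD14 rose in the shEZH2 line (adjusted over the list alone, 2 and 0, and 3 and 1). Median, mean and camera direction differed in sign for PARP family and luminal genes in the shEZH2 line, for recombination, base excision, mesenchymal, antigen presentation, unfolded protein, fibroblast and luminal genes in the shSUZ12 line, and for developmental, mesenchymal and epithelial genes between the lines.

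Further list calls were gained with 1 library left out or the length trend removed. Between the lines, interferon-stimulated genes had 3 of 43 members higher in the shSUZ12 line (adjusted over the list alone, 6, with a median of 0.10). With an estimated correlation camera gave adjusted p = 0.766 with Benjamini-Hochberg adjustment. At the preset correlation it gave 0.198. That camera value was 0.0120 with the length trend removed and 7.67e-05 without shEZH2 replicate 2. In the shSUZ12 line against control, camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0316 for secreted factors without control replicate 1, and 0.0495 for both ribosomal protein and cancer-testis genes without control replicate 2. Without shSUZ12 replicate 2 it gave 0.00277 for secreted factors and 0.00804 for immediate early genes. Between the lines it gave 0.0466 for recombination and 0.0467 for base excision genes without shEZH2 replicate 1, and 0.0391 for matrix proteases and 0.0193 for hypoxia genes without shEZH2 replicate 2. Without shSUZ12 replicate 2 it gave 0.0317 for NF-kB targets and also 0.0317 for secreted factors, 0.0350 for matrix proteases, 0.0255 for hypoxia and 0.00919 for unfolded protein response genes.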

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

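Both tests on cholesterol genes below, of a trend with transcript length and of differences within groups, were chosen after the result was seen. The lists and genes below were called between the depleted lines, and the call of each list was lost with an estimated correlation (camera adjusted p = 0.766 with Benjamini-Hochberg adjustment). CEBPA and MUC5AC were lower in the shSUZ12 than in the shEZH2 line by log2 -6.28 and -5.32, and LRP1 and ADAMTS6 higher by 2.32 and 4.07; in each case the lines also moved in opposite directions from control. In total 216 genes were called between the lines by edgeR. Ribosomal protein genes had a median difference of -0.82 and oxidative phosphorylation genes of -0.60, which were -0.40 and -0.21 without shEZH2 replicate 2. With 2 libraries per group no test for a single library far from its group could be run.

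Cholesterol synthesis genes were lower in the shEZH2 line and higher in the shSUZ12 line, with a median log2 difference of 0.98 between the lines over 25 genes. A trend with transcript length is argued against, since the median stayed at 0.99 ± 0.12 (SE over genes) with each library's length trend removed. A sterol state that varies between cultures as much within a group as between groups remains open: the controls differed from each other by a median of 0.82 ± 0.09, with 24 of 25 genes higher in replicate 2, and this may account for much of the difference. The libraries of the shEZH2 line differed by 0.57 and those of the shSUZ12 line by -0.43. A difference that follows from the targeted subunit also stays open.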

How the results depend on the processing

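The length trend and the sample weights were added after seeing the data. For other settings, the genes called in the shEZH2, shSUZ12 and direct contrasts (957, 228 and 216) were as follows. They were 110, 25 and 14 at adjusted p under 0.01, 236, 117 and 44 against a 1.5-fold change, 1976, 527 and 1304 by DESeq2, 2325, 658 and 1240 with the length trend removed, and 1471 in the shEZH2, 399 in the shSUZ12 and 718 in the direct contrast without the low-count filter. A fit on 2 groups gave 216, 2876 and 1, and sample weights gave 2952 in the shSUZ12 contrast. Other scalings, limma-voom and the 1 CPM filter stayed within 1.5 times. Leaving out 1 library gave 5 to 7775, 9 to 2929 and 0 to 7537. The replicate number as a block gave 1233, 328 and 368 calls. Replicate deviations correlated between groups by 0.116, 0.0930 and 0.165, and nothing in the labels says that a number marks a shared day, so libraries were not paired.

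The shared calls (134) were 20 at adjusted p under 0.01, 315 by DESeq2, 209 with the block, 410 with the length trend removed, and 4 to 1523 with 1 library left out. The correlation of fold changes ranged from 0.502 to 0.679 with 1 library left out. The lists called (5, 5 and 3) were 0, 0 and 0 with an estimated correlation and 0, 0 and 2 by fry (matrix proteases and cancer-testis antigens, neither among the 3), and 6 between the lines with the length trend removed. With the replicate block they were 4, 5 and 4: interferon-stimulated genes were lost in the shEZH2 line and cancer-testis antigens were gained between the lines. Leaving out 1 library gave 2 to 6, 2 to 7 and 4 to 9. Among the named genes, directions turned for 3 that had not passed the test. Without shEZH2 replicate 1 or 2, SUZ12 was at 0.46 or -0.86 between the lines, each value resting on 1 shEZH2 library. In the same fits PHF19 was at 0.19 or -0.00034 in the shEZH2 line, and MKI67 at -1.21 or 0.0192. Of 2546 refits of called named genes, 1919 kept the call, 627 lost it and 0 changed direction. Each fit without 1 library had fewer residual degrees of freedom. Calls rose in every contrast without either shEZH2 library and fell without any other library, so this loss alone does not account for the dependence. In the shSUZ12 contrast the fit on 2 groups, which held no shEZH2 library, gave 2876 calls against 228. The spread between the shEZH2 replicates therefore lowered that count. The cause of the other shifts was not tested.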

Other observations

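The gene groups in the next paragraph, the tests on blood cell genes, and those of transcript length and of mixed RNA in the shEZH2 replicates were chosen after the results that prompted them were seen, and only the test of GC content was written down before.

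Some genes induced by bone morphogenetic protein signalling rose in the shEZH2 line. ID1 stood at 73.4 and 56.9 CPM in control, 175 and 252 CPM in the shEZH2 line and 27.5 and 44.4 CPM in the shSUZ12 line, and rose by 1.71 ± 0.30 in the shEZH2 line. ID2, ID3 and SMAD6, which encodes an inhibitor of the same pathway, rose by 2.55 ± 0.37, 2.03 ± 0.33 and 2.12 ± 0.25. Of 11 such genes 4 rose, 0 fell and 7 were not called in the shEZH2 line, with SMAD7 at -0.03 ± 0.26 and BAMBI at 0.02 ± 0.25, 0 were called in the shSUZ12 line, and 5 were lower in the shSUZ12 than in the shEZH2 line (edgeR, all genes). Of 51 ribosome biogenesis genes, 12 rose and 0 fell in the shEZH2 line and 0 were called in the shSUZ12 line. FTSJ3 and RRP12, both needed for ribosomal RNA processing, rose by 1.40 ± 0.17 and 1.49 ± 0.19.

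The shEZH2 libraries differed from each other more than the other pairs, with an SD of the log2 difference of 0.708 over 13410 genes against 0.354 in control and 0.285 in the shSUZ12 line. Long transcripts were lower in replicate 2: the difference had a Spearman correlation of -0.63 with length across genes, which are not independent, and its median was 0.54 in the shortest and -0.63 in the longest class of 3353 genes. With that trend removed the SD was still 0.562 ± 0.005 (bootstrap SD), and with the trend with GC content removed it was 0.619. These values argue against either measure as the whole cause, although both together took out 46.4% of the variance. Both measures come from the longest annotated transcript of a gene, which may not be the one expressed. The length or GC content of the expressed transcripts therefore stays open. RNA of another group mixed into replicate 2 is argued against by 87.7% of the 2174 genes over 2-fold apart, in which replicate 2 lay outside the range of replicate 1 and the other groups. Such RNA in replicate 1 was not tested, and replicate 2 could lie outside that range in this case too. The source of the rest may be technical or lie in the cells; no biological explanation was tested, since the libraries carry the same labels.

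Some genes best known from blood cells, HCLS1, ARHGAP30, LAPTM5, CXCR4 and PIK3CG, 5 of 10 picked because they were higher, rose in both comparisons. ITGB2, another such gene, fell by 2.20 ± 0.27 and by 4.25 ± 0.31, and the leukocyte list fixed beforehand was not called (camera adjusted p = 0.252 and 0.482 with Benjamini-Hochberg adjustment). RNA of leukocytes in the depleted libraries is argued against: PTPRC and CORO1A together rose by at most 0.301% of the rise of LAPTM5, and PTPRC stayed at or below 0.333 CPM in every library. Of the 28 leukocyte markers fixed beforehand, 16 had no more than 3 counts in any library, and 6 or 7 were over 1 CPM in every library, led by LAPTM5 (up to 374 CPM) and CD68 (up to 113 CPM). Reduction of PRC2 remains a candidate explanation for these 5 genes. It cannot be told apart from loss of PARP1 or from passage of the knockout cells, because no group is depleted of EZH2 or SUZ12 alone.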
